A study of Homo sapiens with 9 samples.

How the data were processed

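RNA levels were measured in HEK293 cells, an established human embryonic kidney line, 72 h after transient transfection with an empty expression vector (PCMV), with Aire or with MBD-VP16. Each of the 3 groups held 3 samples, labelled as separate biological replicates, and each sample gave 1 one-colour array, 9 in all. Per the labels' protocols, the plasmids were delivered with a commercial reagent made for this cell line, total RNA was purified on columns, and the RNA was amplified over the whole transcriptome and labelled with biotin. How the cultures were kept apart is not stated, so the p-values measure the spread between these arrays. For arrays, their number limits the precision: 3 per group.

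The authors deposited log2 expression values, 1 per transcript cluster (a probe set that covers a transcript region) and array, made with RMA per the submitters' processing notes and rounded to 2 decimals in the table used. RMA corrects background, brings the arrays to a common distribution and summarises probes on the log2 scale, which compresses differences of genes with low signal. Its version, the software and the probe annotation release are not given in the sources used here. A further deposited table holds the authors' own comparisons: log2 fold changes, the same changes as a linear ratio, and p-values with false discovery rates, per the file headers. The test behind those p-values is not given in the sources used here. Its 9 per-array columns, whose names carry no sample labels, were not used. The log2 differences of group means computed here lay within 0.0133 of the authors' deposited log2 fold changes in every comparison, with correlations across clusters of 0.999863, 0.999944 and 0.999921.

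Of 28829 clusters in the table, 3150 held no value on any array and were left out, leaving 25679. Gene symbols came from the authors' deposited table: 18683 clusters had 1 symbol and were tested, 2535 had several and 4461 had none. No filter on signal was applied, because the constructs can switch on genes that are silent in vector cells. Symbols were brought up to date through Entrez identifiers with a reference gene table of the GRCh38.p14 assembly, used only for names: 17415 of 17769 identifiers matched and 2719 symbols changed. For the 704 genes with more than 1 cluster, the cluster with the highest mean over the 9 arrays was kept, so that 17769 genes were counted. Of the tested clusters, 922 are annotated in the deposited table as open to cross-hybridisation. Chromosome positions are those of the deposited table, whose genome build is not given in the sources used here.

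One linear model was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no intensity trend), with group as the only factor. The 3 comparisons were Aire against vector, MBD-VP16 against vector and MBD-VP16 against Aire, each with Benjamini-Hochberg adjustment over the 18683 clusters and a threshold of 0.05 on the adjusted p. Standard errors are those of the fit, and SD is that of the 3 arrays of a group. The fit had a prior of 3.64 degrees of freedom and a median standard error of 0.096 on the log2 scale. Tests are two-sided. On simulated data with 50 genes planted per size, the same step recovered 58%, 54% and 76% of changes of 0.5 log2 units in the 3 comparisons in that order, 98%, 98% and 96% of changes of 1, and 100% of changes of 2 or 4, with 6, 14 and 6 false calls among the 18683 clusters.

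Gene lists were written for tissue-restricted genes, genes tied to AIRE or to DNA methylation, stress programmes, markers of other cell types and housekeeping genes. Of 31 lists, the 30 with at least 5 measured genes were tested with camera from limma, at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, 90 tests in all. An estimated correlation and fry, which asks only whether the genes of a list move one way, stood beside it. No list call held with an estimated correlation. Array signals of raised genes were compared with permutation tests of 100000 resamples. Because both comparisons against vector use the same 3 vector arrays, their agreement was set beside 100 simulations of unchanged groups. The vector arrays were simulated as well in these and shared by both comparisons.

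The genes named are those given by a rule: per comparison against vector, the 10 highest and 10 lowest log2 fold changes among genes past the threshold whose 3 arrays all lay above or all below those of the other group; for MBD-VP16 against Aire, 5 and 5; for genes called in both comparisons, the 10 per direction with the largest smaller change; up to 4 members of each list described, by adjusted p; and AIRE and MBD1 always. Genes whose symbol starts with LOC or is an identifier, microRNAs and small nucleolar or nuclear RNAs were counted and not named. A few genes that the rule gives are not reported here. The 4 genes that moved in opposite directions, and the genes and clusters named in the closing observations, were chosen after their values were seen. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

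Alternatives were a replicate block, a repeated quantile normalization, centring of each array, filters on dim clusters, all clusters of the table, clusters counted in place of genes, a prior with intensity trend and robust hyperparameters, array weights, only the 6 arrays compared, stricter thresholds, the authors' own false discovery rates and each array left out in turn. Restricting the test to clusters annotated as unique was added after the data had been seen. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.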

Results

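Expression was profiled in HEK293 cells 72 h after transfection with empty vector, with Aire or with MBD-VP16, on 3 arrays per group. AIRE is the autoimmune regulator, which in the thymus drives the expression of many tissue-restricted genes. MBD is the usual short form of methyl-CpG-binding domain, a fold that binds methylated DNA, and VP16 is a strong viral transcriptional activator; the labels do not spell out the construct. Array medians lay between 6.52 and 6.56 on the log2 scale. Arrays of 1 group correlated at 0.9904 to 0.9948 across genes, Aire with vector arrays at 0.9867 to 0.9911, and MBD-VP16 with vector arrays at 0.9806 to 0.9868. Vector replicate 1 lay farthest from its group, with a residual SD of 0.164 against 0.111 to 0.138 for the other arrays. No arrays held identical values.

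The transcripts of the transfected constructs were examined as a check of the labels. MBD1, a methyl-CpG-binding repressor (chromosome 18, 47793256 to 47807870, in positions of the deposited table, build not named), stood at 9.96 ± 0.138 (SD, n = 3) with MBD-VP16 and at 8.19 ± 0.552 with vector, a 3.43-fold rise (log2 fold change 1.78 ± 0.239, SE; limma adjusted p = 0.0016). The labels do not say which protein the MBD came from, so whether this probe set reads the construct or the cellular gene is open. Vector replicate 2 read 7.55 for MBD1, against 8.49 and 8.52 on the other vector arrays. AIRE (chromosome 21, 45705763 to 45718102) read 6.66, 6.57 and 6.76 on the arrays labelled Aire and 6.32, 6.52 and 6.46 on the vector arrays. This difference of 0.23 ± 0.092 did not pass the test (limma adjusted p = 0.174), although all 3 values lay above those of vector. The species and extent of the transfected sequences are not given in the labels, so this probe set may not read the construct, and directions given for Aire rest on the labels alone.

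Aire was compared with vector to find which genes its transfection raised or lowered. ANKRD1, a transcriptional cofactor with ankyrin repeats, dropped 6.05-fold in the arrays labelled Aire, from 10.82 ± 0.05 to 8.22 ± 0.07 (SD, n = 3). The matricellular genes CCN2 and CCN1 fell by 1.85 ± 0.09 and 1.38 ± 0.08 log2 units (SE), and the secretory granule gene SCG3 and the neural gene BEX1 fell by 1.73 ± 0.13 and 1.42 ± 0.14. TMT1A, a thiol methyltransferase, rose 2.30-fold and SCN9A, a voltage-gated sodium channel, 2.12-fold, while IGFBP5, an insulin-like growth factor binding protein, rose by 1.05 ± 0.15 and the proteoglycan gene VCAN by 0.93 ± 0.09. CGA, the shared subunit of the glycoprotein hormones, rose 2.01-fold.

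Among other genes named for this comparison, ETV5 (−1.40), SNAPC1 (−1.15) and MMP19 (−1.10) fell and PARM1 (0.99) and NREP (1.04) rose. The cluster for RFPL4A showed the largest change of a named gene, −2.62 ± 0.08 (limma adjusted p = 5.4e-07), and it is annotated as open to cross-hybridisation, as is that for NREP; whether the RFPL4A probes also read plasmid sequence was not tested. The calls for OSTN (1.21), PCDHB8 (0.98) and KRTAP21-2 (0.93) were weak: each was lost when any 1 of 8 of the 9 arrays was left out, with adjusted p up to 0.114, 0.131 and 0.14.

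In all, 1253 of 17769 genes changed with Aire (limma adjusted p under 0.05), 439 higher and 814 lower, and 4012 had an unadjusted p under 0.05. Changes were small: 6 genes rose and 23 fell at least 2-fold. The share of higher genes was 35%, and 44% after a repeated quantile normalization. All 1253 had 3 arrays clear of the other group; among all genes 26.8% did, where chance gives 10%. Without vector replicate 1 the count was 862, and leaving out Aire replicate 2 gave the lowest, 457. The authors' deposited table calls 975 genes at the same threshold on its false discovery rate, 326 higher and 649 lower, of which 958 were also called here.

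Lists tied to AIRE itself moved little. None of 17 measured genes reported as induced by Aire in transfected lines passed the test, over all genes or adjusted over the list alone (camera adjusted p = 0.357), nor did any of 28 autoantigens of AIRE deficiency (0.466). Of 30 genes for AIRE partner proteins, 2 rose and 2 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.549): TOP2A (0.29) and MSN (0.28), and JMJD6 (−0.47) and CCNT1 (−0.37). The call for MSN was lost whichever of the 9 arrays was left out, and those for TOP2A and CCNT1 with any 1 of 6. Among tissue lists, 0 of 65 epidermal, 41 gut and 43 retina and lens genes passed; 3 of 71 liver genes rose (1 adjusted over the list alone), among them PCK1 (0.72), the gluconeogenic enzyme, and 2 of 37 pancreas genes (1 adjusted over the list alone), CEL (0.70), a secreted lipase, and PAX6 (0.29). SCG3 and SCG2 (−0.48) fell among 60 neuronal genes, and NPPB (−0.81), ACTN2 (−0.77) and TPM1 (−0.36) among 49 muscle genes. Of 74 cancer-testis and germline genes, TEX19 (0.43) rose and SOHLH2 (−0.58) fell (0 and 1 adjusted over the list alone). Camera adjusted p for these 8 tissue lists ranged from 0.288 to 0.961. The calls for PAX6, TPM1 and TEX19 were each lost when any 1 of 8 of the 9 arrays was left out, with adjusted p up to 0.154, 0.133 and 0.122. Of 32 leukocyte markers, CD52 (0.46) rose and IL2RG (−0.52), whose call was lost with any 1 of 5 arrays left out, fell (0.466), and none of 20 fibroblast and endothelial markers passed (0.238).

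Immediate early genes, which respond within minutes to growth factors or stress, were lower as a list with Aire. Of 24 measured, 7 fell and none rose, the same counts as adjusted over the list alone: CCN2, CCN1, EGR1 (−0.98), DUSP1 (−0.84) and 3 more (median −0.14, mean −0.32; camera adjusted p = 9.46e-06; adjusted p = 0.193 with an estimated correlation). The clustered protocadherins, neural cell-surface adhesion genes, were higher: 5 of 15 rose (7 adjusted over the list alone), with PCDHB13 at 0.83 ± 0.11, PCDHB11 at 0.80 ± 0.13, PCDHB2 at 0.58 ± 0.12 and PCDHB7 at 0.39 ± 0.09 (SE), and none fell (median 0.38; camera adjusted p = 9.46e-06; adjusted p = 0.193 with an estimated correlation). Metallothioneins, which bind metal ions, were higher as well: MT1X (0.40), MT1F (0.41) and MT2A (0.33) rose of 13 measured, 8 adjusted over the list alone (median 0.30; camera adjusted p = 2.49e-05; adjusted p = 0.399 with an estimated correlation). Of 46 interferon-stimulated genes 8 rose and none fell (11 adjusted over the list alone), among them IFI6 (0.79), BST2 (0.73), STAT2 (0.53) and IFI44L (0.92). That list's camera adjusted p was 0.0238, or 0.0706 after a repeated quantile normalization, the call was also lost without vector replicate 3 or Aire replicate 1, and the adjusted p = 0.825 with an estimated correlation. Of the members named for these 4 lists, PCDHB7 lost its call when any 1 of 6 of the 9 arrays was left out, PCDHB2 and MT2A with any 1 of 5, MT1F with any 1 of 4 and IFI44L with either of 2.

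Other lists did not pass in this comparison. Of 24 heat shock genes 1 rose and 5 fell (4 and 6 adjusted over the list alone), with HSPB8 (−0.95) and HSPH1 (−0.55) lowest in adjusted p (camera adjusted p = 0.0852). Among 29 inflammatory genes NFKB1 (−0.64), BIRC3 (−0.94), NFKB2 (−0.41) and RELB (−0.52) fell (0.0852, and 0.0454 after a repeated quantile normalization), the calls for RELB being lost whichever array was left out and for NFKB2 with any 1 of 5. Of 23 cholesterol synthesis genes STARD4 (0.50) and SREBF2 (0.31), the latter lost with any 1 of 5 arrays left out, rose (0.0852, and 0.0167 after that normalization). The replication licensing genes MCM6 (−0.46) and MCM5 (−0.58) were among 8 of 52 cell cycle genes that fell, while 3 rose, PLK1 (0.45) among them (5 up and 11 down adjusted over the list alone; 0.549). Of 28 p53 target genes 4 rose, CDKN1A (0.53) and TP53INP1 (0.53) among them, and 4 fell, with GADD45B at −0.85 (7 and 5 adjusted over the list alone; 0.753). In 29 genes of the unfolded protein response PPP1R15A (−0.95) and ATF3 (−0.47) were among 4 that fell, and PDIA4 (0.51) rose (5 up and 5 down adjusted over the list alone; 0.961). In the list of 16 genes written for DNA methylation writers and erasers, APOBEC3B (0.74), a cytidine deaminase, and MAT2A (0.30) rose. GADD45B and GADD45A (−0.27) fell there, the call for GADD45A being lost with any 1 of 7 arrays left out. That list, whose name does not describe each member, held 2 up and 3 down when adjusted over it alone (camera adjusted p = 0.862). CBX5 (0.38) rose in the list of 26 methyl-CpG readers and corepressors (camera adjusted p = 0.961). Of 48 replication-dependent histone genes 2 rose, H3C11 (0.49) among them, and 3 fell (5 and 5 adjusted over the list alone; 0.316), and ZDBF2 (0.61) rose among 28 imprinted genes (0.961). Median, mean and test of a list differed in sign for the neuronal, muscle, unfolded protein response, cell cycle, respiratory chain and methyl-CpG reader lists.

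MBD-VP16 was compared with vector, which asks which genes the fusion raised or lowered. RFPL4B, a ret finger protein-like gene, rose 26.7-fold, from 3.10 ± 0.17 to 7.84 ± 0.02 (SD, n = 3). ZNF750, a regulator of epidermal differentiation, rose 12.9-fold, the homeobox gene TPRX1 9.67-fold and the neurofilament genes NEFH and NEFM 9.34-fold and 5.27-fold. CCNA1, the germline cyclin A1, rose by 3.02 ± 0.12 log2 units (SE), and ZSCAN4, a zinc finger gene of the early embryo, by 2.83 ± 0.17. The vector signals of RFPL4B, ZSCAN4 and ZNF750 were low (3.10, 3.56 and 4.21), where background compresses differences, so these folds are best read as lower bounds. H3Y2 (2.70), TRIM48 (2.47) and the homeobox gene DUXA (2.45) completed the 10 highest. ANKRD1 dropped 4.27-fold and BEX1 4.16-fold, and SCG3, CPNE4, a copine, and NPR3, a natriuretic peptide receptor, fell by 1.60 ± 0.13, 1.37 ± 0.14 and 1.20 ± 0.09.

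With MBD-VP16, 2413 of 17769 genes changed (limma adjusted p under 0.05), 1051 higher and 1362 lower, and 4944 had an unadjusted p under 0.05. At least 2-fold changes were mostly rises, 105 against 23 falls. The share of higher genes was 43.6%, and 32.6% when each array was centred on its median. Of the changed genes 2402 had arrays clear of the other group; among all genes 30.9% did, where chance gives 10%. Without vector replicate 1 the count was 1739, and leaving out MBD-VP16 replicate 2 gave the lowest, 1305. The authors' deposited table calls 1973 genes at the same threshold, 848 higher and 1125 lower, of which 1943 were also called here.

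Among the lists written in advance, the clustered protocadherins had the lowest camera p with MBD-VP16: 12 of 15 rose, also when adjusted over the list alone, and none fell (median 0.80; camera adjusted p = 1.41e-09; adjusted p = 0.058 with an estimated correlation). PCDHB7, PCDHB2, PCDHB11 and PCDHB13 rose by 0.80 ± 0.09, 1.01 ± 0.12, 0.95 ± 0.13 and 0.78 ± 0.11 log2 units (SE). Interferon-stimulated genes were higher, with 10 of 46 up and 1 down (13 and 2 adjusted over the list alone): BST2 (1.03), USP18 (0.82), ISG15 (0.97) and IFI6 (0.69) led by adjusted p (camera adjusted p = 5.54e-04; adjusted p = 0.399 with an estimated correlation). Metallothioneins had the same p-values, with MT1F (0.64), MT1G (0.43) and MT2A (0.28) up of 13, 7 adjusted over the list alone; the call for MT2A was lost with any 1 of 7 arrays left out. Of 48 replication-dependent histone genes 8 rose and 1 fell (9 and 1 adjusted over the list alone), with H3C11 at 0.38, H2BC10 at 0.48, H2AC14 at 1.03 and H3C8 at 0.48 (camera adjusted p = 0.00737; adjusted p = 0.399 with an estimated correlation).

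Heat shock genes were lower with MBD-VP16: 6 of 24 fell and none rose (8 and 3 adjusted over the list alone), among them HSPB8 (−0.87), HSPH1 (−0.51), BAG3 (−0.34) and HSPA4 (−0.29). Their camera adjusted p was 0.0255, or 0.114 after a repeated quantile normalization, and the adjusted p = 0.763 with an estimated correlation. FBN1 (0.44) and PDGFRA (0.71), markers of fibroblasts, rose of 20 fibroblast and endothelial markers, also when adjusted over the list alone (camera adjusted p = 0.0306, or 0.145 after that normalization; adjusted p = 0.763 with an estimated correlation). The calls for the heat shock list and for this one were also lost without vector replicate 1 or MBD-VP16 replicate 2. Leukocyte markers did not pass as a list (0.496), with CD52 and CD68 both at 0.64 the 2 that rose of 32.

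Single tissue-restricted genes changed with MBD-VP16 inside lists that did not pass. Of 60 neuronal genes 7 rose and 4 fell, with ELAVL3 at 0.92 besides NEFH and NEFM (camera adjusted p = 0.0795, and 0.0496 with centred arrays). Of 74 cancer-testis and germline genes 5 rose and 3 fell: DPPA3 (1.94), a germ cell and preimplantation gene, BRDT (1.20), a testis bromodomain protein, and TKTL1 (0.84) were up and SOHLH2 (−0.57) was down (0.0667, and 0.0454 with centred arrays). This list, like the others, holds only genes on clusters with 1 symbol, so genes read only by clusters with several symbols are not covered. Of such clusters 243 rose and 127 fell with MBD-VP16 in a fit over all clusters. A cluster of the cancer-testis family GAGE rose by 6.86 in that fit. Imprinted genes held 5 that rose, DLX5 (1.49), DLK1 (1.03), H19 (0.89) and PEG10 (0.44) among them, and 2 that fell, of 28 (0.105). NKX2-2 (1.29) and CEL (0.88) were among 4 of 37 pancreas genes that rose, while 1 fell (0.138), and ATP4B (0.61), a subunit of the gastric proton pump, was among 3 of 41 gut genes that rose (1 adjusted over the list alone; 0.101). TNNC2 (1.10), of the troponin complex, was among 5 of 49 muscle genes that rose, while NPPB (−0.93) was among 2 that fell (0.222). SFN (0.79) and CNFN (0.66) rose of 65 epidermal genes (0.286), PCK1 (0.75) was among 3 of 71 liver genes that rose while OTC (−0.49) fell (1 and 1 adjusted over the list alone; 0.657), and 0 of 43 retina and lens genes passed (0.189).

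Of the 17 genes reported as induced by Aire in transfected lines, MUC4 (0.49) rose with MBD-VP16 (camera adjusted p = 0.138), and of 28 autoantigens of AIRE deficiency 2 rose, SOX10 (0.34) among them (0.428). AIRE partner genes held 2 that rose and 3 that fell of 30 (0.503). APOBEC3B (0.91) was the 1 riser in the list of 16 genes written for DNA methylation writers and erasers. GADD45A (−0.45), UHRF2 (−0.56) and GADD45B (−0.38) fell there, the last lost with any 1 of 5 arrays left out. Adjusted over that list alone 1 rose and 4 fell (camera adjusted p = 0.738). CBX5 (0.27) and MBD1, whose rise may be that of the construct, were up in the list of 26 methyl-CpG readers and corepressors. TRIM28 (−0.21) fell in it, a call lost whichever array was left out (2 up and 0 down adjusted over the list alone, camera adjusted p = 0.711). Of 24 immediate early genes 2 rose and 8 fell, with CCN1 (−1.12), DUSP1 (−0.96), CCN2 (−1.14) and ATF3 (−0.71) lowest in adjusted p (3 and 8 adjusted over the list alone; 0.138). Of 29 unfolded protein response genes 2 rose and 6 fell, PPP1R15A (−1.10) among them (2 and 8 adjusted over the list alone; 0.0667, and 0.0496 with centred arrays). ICAM1 (0.74) was among 3 of 29 inflammatory genes that rose, and NFKB1 (−0.68) and NFKB2 (−0.50) fell (0.739). BNIP3 (1.04) was among 4 of 24 hypoxia genes that rose, and KDM3A (−0.50) among 4 that fell (5 and 7 adjusted over the list alone; 0.987). MCM6 (−0.36) and MCM2 (−0.39) were among 12 of 52 cell cycle genes that fell, while 2 rose (13 and 2 adjusted over the list alone; 0.101), CDKN1A (0.48) among 6 of 28 p53 targets that rose while 5 fell (7 and 5 adjusted over the list alone; 0.524), and TM7SF2 (0.32) alone rose of 23 cholesterol synthesis genes (0.138). The hypoxia and methyl-CpG reader lists differed in sign between median and mean.

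**Figure D1:**
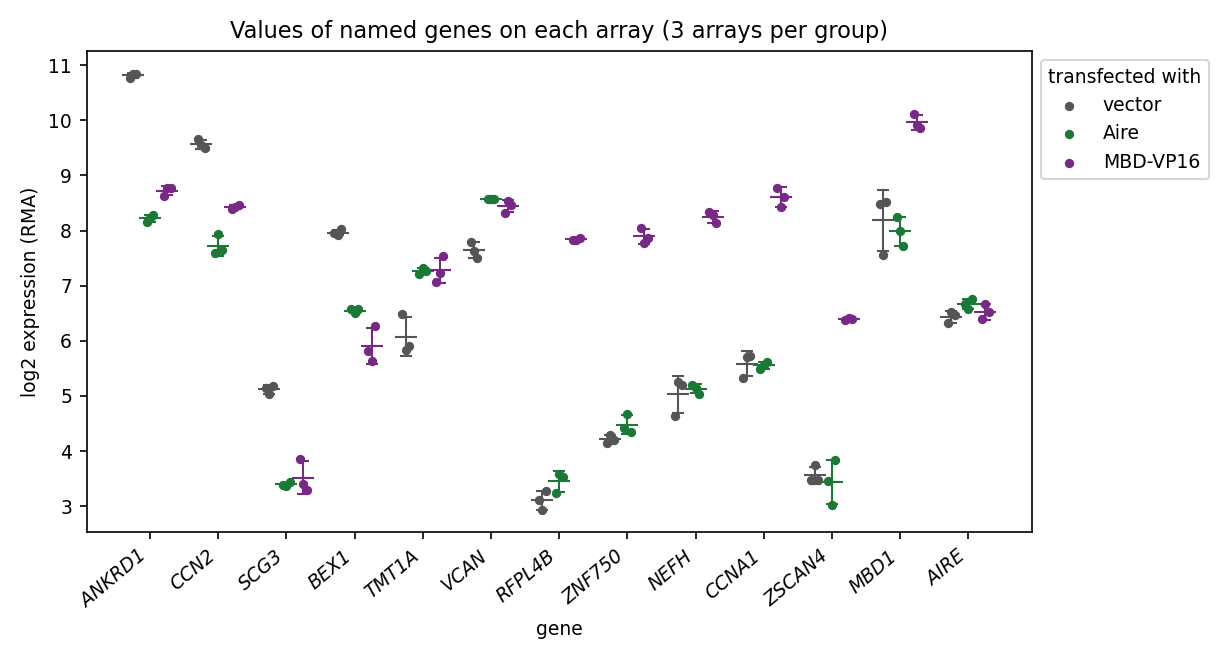
Log2 expression of named genes on each of the 9 arrays, with points for arrays and bars for the mean ± SD of the 3 arrays of a group. ANKRD1 read 10.82 on average with vector and 8.22 with Aire, RFPL4B 3.10 with vector and 7.84 with MBD-VP16, and the AIRE values of the groups differed by 0.23 between Aire and vector.

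The direct comparison of MBD-VP16 with Aire asks where the constructs differed from each other. RFPL4B stood 4.39 ± 0.11 log2 units (SE) and RFPL4A 3.74 ± 0.08 above the arrays labelled Aire, and ZNF750, TPRX1 and NEFH 10.7-fold, 10.4-fold and 8.71-fold above, where low signals with Aire again make the values for RFPL4B and ZNF750 lower bounds. In total 317 genes differed (limma adjusted p under 0.05), 299 higher and 18 lower with MBD-VP16, 78 and 1 of them by at least 2-fold, and 2046 had an unadjusted p under 0.05. KRTAP21-2 (−1.24), BEX1 (−0.64), S100A5 (−0.59), SCN9A (−0.57) and ZNF711 (−0.56) were lower with MBD-VP16, and each of these 5 calls was lost when at least 5 of the 9 arrays were left out in turn. All 317 had arrays clear of the other group; 19.8% of all genes did, where chance gives 10%. The authors' deposited table calls 296 genes, 280 higher and 16 lower, of which 272 were also called here.

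Immediate early genes were higher with MBD-VP16 than with Aire as a list, with EGR1 (1.13), a zinc finger transcription factor, IER3 (0.62) and CCN2 (0.71) up and JUN (−0.36) down of 24 (5 and 3 adjusted over the list alone; median 0.12; camera adjusted p = 8.43e-04; adjusted p = 0.335 with an estimated correlation). Protocadherins were higher, PCDHB6 (1.39) and PCDHB7 (0.41) of 15 passing and 4 adjusted over the list alone, although these 2 calls were lost with any 1 of 5 and of 7 of the 9 arrays left out, with adjusted p up to 0.126 and 0.176 (median 0.22; camera adjusted p = 7.99e-05; adjusted p = 0.165 with an estimated correlation). Neuronal genes were higher, with NEFH, NEFM (2.54), ELAVL3 (1.05) and INA (1.65) among 5 of 60 that rose and none that fell (6 and 1 adjusted over the list alone; mean 0.16, median 0.02, or −0.00167 with centred arrays; camera adjusted p = 0.0339; adjusted p = 0.927 with an estimated correlation). This call was lost without Aire replicate 1 or 2 or MBD-VP16 replicate 2 and when the dimmer genes were left out. A replicate block also ended this call, and that for the imprinted genes. Imprinted genes were called higher with 5 of 28 up, also when adjusted over the list alone, DLX5 (1.46), PEG10 (0.50), DLK1 (1.00) and H19 (0.59) among them; their mean was 0.13 but their median −0.015 (camera adjusted p = 0.045; adjusted p = 0.676 with an estimated correlation), a call lost with any 1 of 6 of the 9 arrays left out and without the dimmer genes. Genes of the unfolded protein response were called lower with a median of −0.11 (camera adjusted p = 7.99e-05; adjusted p = 0.0881 with an estimated correlation), although the 1 member of 29 that passed, CRELD2 (0.56), rose, a call lost with centred arrays (1 up and 1 down adjusted over the list alone). The calls for CRELD2, JUN and H19 were lost with any 1 of 7, 6 and 5 of the 9 arrays left out. The members ATF3 (−0.23), PDIA6 (−0.22) and TRIB3 (−0.23) did not pass. Of 74 cancer-testis and germline genes 4 were higher and none lower, DPPA3 (1.73), BRDT (1.20), TKTL1 (0.87) and TEX14 (0.64) (5 and 1 adjusted over the list alone; camera adjusted p = 0.0559, and 0.0293 with centred arrays).

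The 2 comparisons against vector were then set side by side, to see whether both constructs raised and lowered the same genes. TMT1A rose 2.30-fold with each, and SEMA6A, a semaphorin, by 0.87 with Aire and 1.01 with MBD-VP16. TMSB15A (0.82 and 0.86), INPP5D (0.79 and 0.76) and VCAN (0.93 and 0.80) rose with both, as did PCDHB8, PCDHB11, PCDHB13 and NREP. Among genes that fell with both were ANKRD1, SCG3, BEX1, CCN2 and CCN1, the cytokine receptor gene TNFRSF12A (−1.05 and −1.06), the matrix metalloproteinase gene MMP19 (−1.10 and −1.07), CFAP69 (−1.09 and −1.19) and CPNE4 (−1.02 and −1.37).

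In both comparisons 287 genes were higher, 65.4% of those raised with Aire and 27.3% of those raised with MBD-VP16, where independent lists would share 26. In both, 662 were lower, 81.3% and 48.6% of those lowered, where independent lists would share 62.4. With 1 array left out the counts were lowest without Aire replicate 2, at 121 genes higher and 267 lower with both. No gene was higher with Aire and lower with MBD-VP16, where 33.6 would be shared by independent lists. The reverse held for 4 genes, against 48.1 for independent lists: CHKA, a choline kinase (−0.44 with Aire and 0.41 with MBD-VP16), RBP7 (−0.31 and 0.49), RFPL4A (−2.62 and 1.12, with the doubt about its probes given above) and the glucose transporter gene SLC2A3 (−0.39 and 0.45). Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.657 and Spearman's rho = 0.72, and 77.4% had the same sign. Unchanged groups simulated with 1 spread per gene, sharing simulated vector arrays, gave r = 0.499 (0.478 to 0.519 over 100 simulations) and 66.6% of the same sign. The real vector arrays spread more, with residual SDs of 0.164, 0.122 and 0.138 against 0.111 to 0.121 for the others. The simulation may therefore understate what sharing adds. The covariance was 0.037 against 0.00627 simulated, a difference of 0.0308. The 3 vector arrays cannot be split into sets of at least 2, so part of the excess may come from the shared controls.

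Tested directly, few of the shared genes differed between the constructs: 19 of the 287 higher with both, 17 of them further up with MBD-VP16, and 7 of the 662 lower with both. Of the 1051 genes raised with MBD-VP16, 254 stood above Aire in the direct comparison, RFPL4B and NEFH among them, and 2 stood below it. Of the 439 genes raised with Aire, 23 differed between the constructs. A p that misses the threshold does not show that the constructs acted alike. In data simulated with the same spread for each comparison, 54% to 76% of changes of 0.5 log2 units were recovered.

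**Figure D2:**
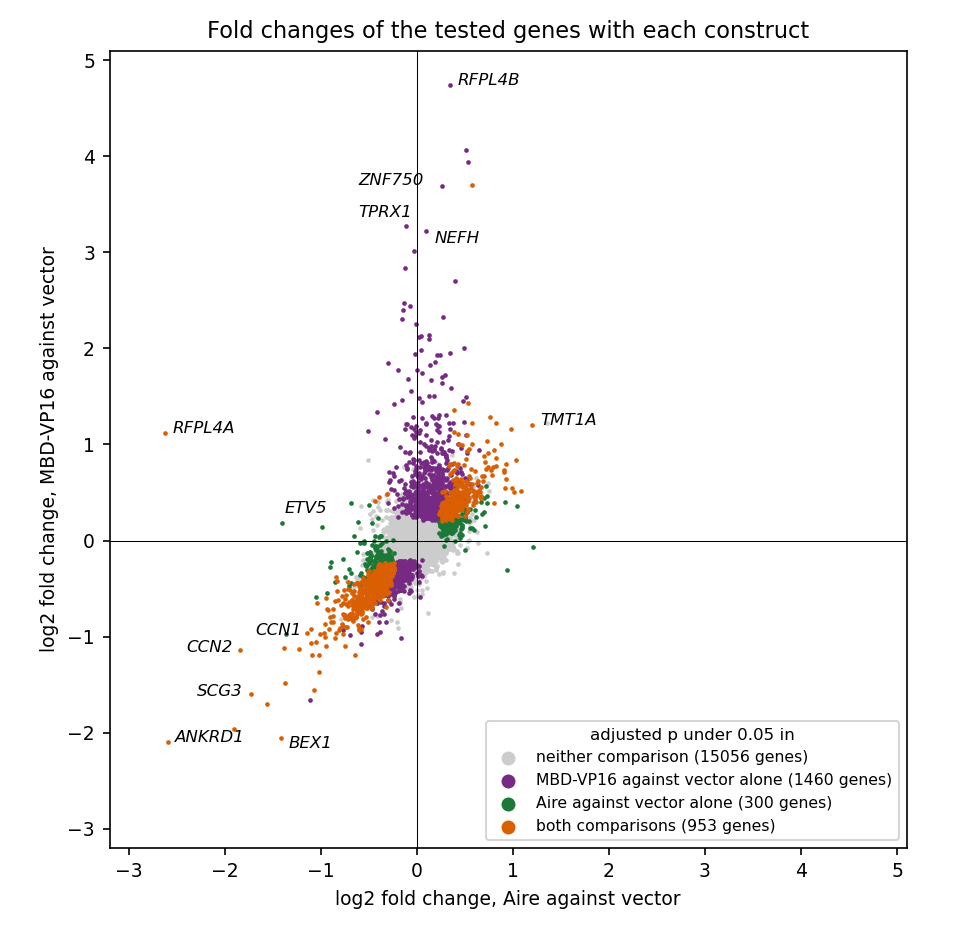
Log2 fold change of each of 17769 genes with Aire against vector (horizontal axis) and with MBD-VP16 against vector (vertical axis), coloured by the comparison in which the limma adjusted p was under 0.05. Of the genes past it in both, 287 lie at upper right and 662 at lower left, while RFPL4B and ZNF750 lie high on the vertical axis near 0 on the other.

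**Figure D3:**
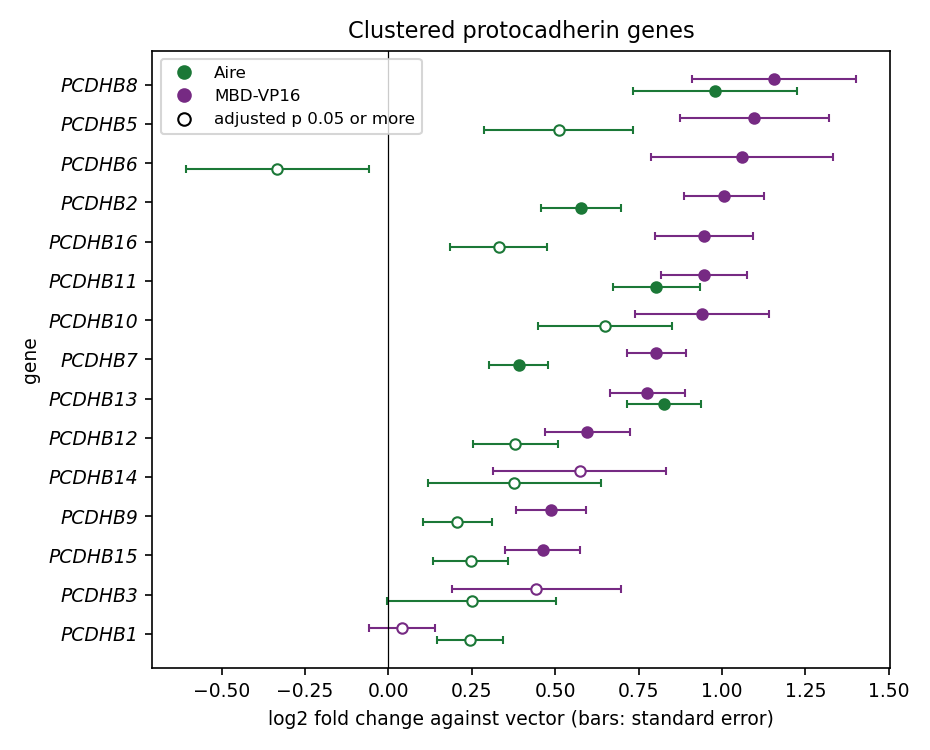
Log2 fold change against vector of the 15 measured clustered protocadherin genes, with the standard error as bars, filled where the adjusted p was under 0.05. With MBD-VP16 12 of 15 are filled and with Aire 5.

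The array signal of the raised genes was compared with that of other genes, to see whether the constructs raised genes of low or of high signal. Signals of different probe sets also depend on probe affinity and background, so they give no ranking of genes by expression. The permutations draw genes and not arrays, so their p-values do not measure the spread between arrays. Genes raised with Aire, such as VCAN and NREP, had a median signal over all 9 arrays of 7.62, against 6.55 for all tested genes. The difference was 1.07 (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). Against the 7.97 of genes that fell it was −0.35 (permutation p = 8e-05). Genes that fell with Aire lay 1.42 above all tested genes (permutation p = 1e-05), so a signal above theirs was not particular to raised genes. The 1.07 was 0.541 without vector replicate 3 and 0.205 when the dimmer genes were left out, and the −0.35 was −0.796 without that array, −0.907 with signal from the vector arrays alone and −0.0511 when the dimmer genes were left out (permutation p = 0.342), which ended that call. Genes raised with MBD-VP16, such as RFPL4B and ZSCAN4, had a median of 6.79, which was 0.24 above all genes (permutation p = 0.00166) and 1.13 below the 7.92 of genes that fell, a difference of −0.328 with the dimmer genes left out. That 0.24 turned to −0.0067 when signal was taken from the vector arrays alone and to −0.0823 when the dimmer genes were left out. Signal from the vector arrays alone shares its error with the fold change and leaves out the arrays that carry the change. Against vector it is therefore lower for raised genes and higher for lowered genes by construction, and its shifts give no separate evidence. Genes higher with MBD-VP16 than with Aire had a median of 6.4, not separable from all genes by the test (−0.15; permutation p = 0.289), although the difference was −0.557 with signal from the vector arrays alone (permutation p = 0.001). That setting leaves out the MBD-VP16 arrays, on which these genes were higher.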

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

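The tests in this part followed a setting planned in advance, a fit over all clusters of the table, and the single clusters named were picked only after their values had been seen. Clusters outside the comparisons of named genes, because the deposited table gives them no gene symbol or several, also rose above the vector arrays. With Aire 42 clusters without a symbol and 46 with several symbols were higher than with vector (limma adjusted p under 0.05), while 26 and 78 were lower. With MBD-VP16 these numbers were 65 and 243 higher, and 54 and 127 lower. Among the clusters with several symbols, 132 were higher with MBD-VP16 than with Aire and 1 was lower. The largest rise with MBD-VP16 was 6.86 ± 0.17 log2 units (SE) on a cluster whose 17 symbols belong to the GAGE family of cancer-testis antigens (chromosome X, 49195253 to 49195366, in positions of the deposited table, build not named). Pairs of clusters for the TRIM64 and TRIM43 families rose by 6.35 ± 0.17 and by 5.52 ± 0.22 and 5.50 ± 0.27 with MBD-VP16, and the TRIM43 clusters by 1.22 ± 0.22 and 1.18 ± 0.27 with Aire. Both TRIM64 clusters gave the same change, SE and adjusted p, so they may repeat 1 reading. The counts of clusters with several symbols can hold such repeats. A cluster of 72 bases without a symbol (chromosome 16, 3202609 to 3202680) fell by 2.46 ± 0.14 with Aire and by 2.90 ± 0.14 with MBD-VP16. It was 1 of 5 and of 7 that fell among 191 clusters of 70 to 76 bases named only by their position. Of these 191 clusters 4 rose with Aire and 3 with MBD-VP16, and their median changes were 0.04 and 0.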

How the results depend on the processing

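The tests on clusters annotated as unique were added after the data had been seen; all other settings were planned. The AIRE and MBD1 differences kept their side of the threshold in all 90 refits, and of the refits of named genes none reversed, 5391 kept their side, 579 lost the call and 135 gained one. Genes changed with Aire numbered 2079 without the dim clusters, those below the median level, 2181 with a trend and robust prior, 603 from only the 6 arrays compared, 287 at adjusted p under 0.01 and 207 with at least 1.5-fold change, and 457 to 1086 with 1 array left out (695 without vector replicate 2, 543, 457 and 483 without Aire replicates 1, 2 and 3). With MBD-VP16 they were 1567 from 6 arrays, 920 at 0.01, 500 at 1.5-fold and 1305 to 2256 with 1 array left out (1305 and 1432 without MBD-VP16 replicates 2 and 3), and for MBD-VP16 against Aire 483 with trend, 157, 190 and 193 to 369 (195 and 194 without Aire replicates 2 and 3, 193 and 200 without MBD-VP16 replicates 2 and 3). Stricter thresholds lower counts by construction. Fewer arrays lowered most of these counts but not all: 369 genes differed between MBD-VP16 and Aire without vector replicate 1, against 317 with all arrays. Apart from the thresholds the cause was not tested. Genes higher with both numbered 505 without dim clusters, 517 with trend, 70 at 0.01 and 976 at unadjusted p under 0.05, and 121 to 254 with 1 array left out (174 without vector replicate 2, 126, 121 and 124 without Aire replicates 1, 2 and 3, 184, 171 and 153 without MBD-VP16 replicates 1, 2 and 3). Genes lower with both numbered 1106, 1137, 170 and 1672, and 267 to 606 (388 and 377 without vector replicates 1 and 2, 325, 267 and 280 without Aire replicates 1, 2 and 3, 427 without MBD-VP16 replicate 3). The correlation was 0.773 without dim clusters and 0.627 to 0.71 with 1 array left out.

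With an estimated correlation 0 lists were called in each comparison, against 4, 6 and 5. By fry the interferon list with Aire (fry adjusted p = 0.0611) and the fibroblast and endothelial list with MBD-VP16 (0.146) did not pass. Neither did the neuronal (0.164) and imprinted (0.101) lists for MBD-VP16 against Aire. Fry called immediate early (0.00635) and unfolded protein response genes (0.000628) lower and imprinted genes (0.0405) higher with MBD-VP16 against vector. With 1 array left out 3 to 5, 4 to 11 and 3 to 8 lists were called; 11 came without vector replicate 3, 10 without vector replicate 2 or MBD-VP16 replicate 1, and 3 and 8 without Aire replicate 2 and MBD-VP16 replicate 3. For MBD-VP16 against Aire 3 were called without dim clusters. The signal of genes raised with Aire minus that of genes lowered was −0.0511 without dim clusters, −0.907 on the vector arrays' signal and −0.796 to −0.242 with 1 array left out, and minus all genes 0.205 without dim clusters and 0.541 to 1.12. For MBD-VP16 the difference from all genes reversed to −0.0823 without dim clusters, −0.0067 on the vector arrays' signal and −0.0166 without vector replicate 3 (up to 0.395), its call was lost at 0.0811 without MBD-VP16 replicate 3, and that from lowered genes was −0.328 without dim clusters and −1.64 on the vector arrays' signal and ran from −1.3 to −0.963 with 1 array left out. For MBD-VP16 against Aire the difference from all genes became significant at −0.423 and −0.557 in those settings and ran from −0.418 to −0.154 (−0.366 and −0.413 without Aire replicates 2 and 3, −0.393 and −0.418 without MBD-VP16 replicates 2 and 3). Shifts on the vector arrays' signal are in part built in, as given above. The replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at −0.067 to 0.172, and 1 of 9 arrays correlated best with its own number in both other groups. A replicate block gave 928, 2152 and 255 changed genes and 3 lists for MBD-VP16 against Aire, without those of neuronal and imprinted genes (camera adjusted p = 0.0509 and 0.0574), with 28 named-gene calls lost and 3 gained.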

Other observations

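All tests of gene groups in this part were chosen after results had been seen, apart from the splits of the arrays, and the tests of probes shared between gene copies and of the fit without vector replicate 1 were also set after their values had been seen. HOX cluster genes, which pattern the body axis, rose with MBD-VP16: 18 of 37 measured passed the test and none fell (25 adjusted over the list alone; median 0.36; camera p = 1.41e-15, and p = 0.000153 with an estimated correlation). HOXC11 (1.23 ± 0.08, SE), HOXB6 (1.22 ± 0.12), HOXA11 (1.16 ± 0.12) and HOXA5 (0.97 ± 0.08) were among them. With Aire 1 of the 37, HOXA3 (0.30 ± 0.07), rose, with a list median of 0.07 (camera p = 0.0401, and p = 0.0737 with an estimated correlation), and in the direct comparison 12 were higher with MBD-VP16 and none lower (p = 6e-05 with an estimated correlation). Of the 35 members whose values had not been looked at when the list was written, 17 rose with MBD-VP16.

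Some target genes of the YAP and TEAD transcriptional regulators were lower with both constructs. With Aire 10 of 22 fell and 1 rose (11 and 1 adjusted over the list alone; median −0.23; camera p = 1.32e-08, and p = 0.000876 with an estimated correlation), and with MBD-VP16 11 fell and 2 rose (median −0.28; camera p = 1.91e-06, and p = 0.00218 with an estimated correlation). ANKRD1, CCN2, CCN1, MYOF (−1.10 with Aire and −0.92 with MBD-VP16), TGFB2 (−0.92 and −0.92) and AMOTL2 (−0.76 and −0.51) fell with each. The list was written after the falls of ANKRD1, CCN1, CCN2, MYOF and TGFB2 were known, and CCN1, CCN2 and GADD45A also stand in lists used above. Of the 17 members other than those whose falls were known, 5 fell and 1 rose with Aire (camera p = 0.00882, and p = 0.0435 with an estimated correlation). With MBD-VP16 6 of the 17 fell and 2 rose, and the shift was lost with an estimated correlation (camera p = 0.0266, and p = 0.0742). GADD45A was counted among the 17, although it had been tested in a list used above, where it fell with both constructs. The 17 are therefore not a set of wholly unseen members.

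Targets of DUX4, a double homeobox factor of the cleavage-stage embryo, were higher with MBD-VP16, 21 of 24 measured passing and none falling (median 1.99), among them CCNA1, ZSCAN4, TPRX1, PRAMEF2 (1.98 ± 0.15) and ZNF280A (2.26 ± 0.14), but the list was written when all but 4 members had been seen. Hybridisation between gene copies is argued against as the whole cause, since members on clusters annotated as unique had a median of 2.12, with 17 of 20 up, all 17 of them seen before. Genes matched on signal had a median of 0.0333. The matching used the mean signal over all arrays, which includes the MBD-VP16 arrays where the targets rose. The matched genes can therefore be brighter than the targets were in vector cells, so a general rise of dim genes is left undecided. The hypothesis that MBD-VP16 may raise a DUX4-like programme as a whole was tested on the 4 unseen members, whose median was 0.617 (camera p = 0.00198, and p = 0.0201 with an estimated correlation). Only PRAMEF10 (1.36 ± 0.10) of these passed, on a cluster not annotated as unique, while ZNF705A (0.81 ± 0.33), RFPL2 (0.42 ± 0.15) and CXCR4 (0.21 ± 0.16) on unique clusters did not, so the evidence from unseen members is thin. The 12 clusters that list DUX4 among several symbols showed 0 calls (median −0.12 with MBD-VP16), and a direct action of the fusion on these genes stays open, as binding was not measured.

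The genes lower with both constructs could owe their overlap to the vector arrays they share. A fit that never used vector replicate 1 still called 388 genes lower with both, where independent lists would share 24.1, and 370 of them were among the 662, so that array is argued against as the whole cause, although the count was smaller and the other vector arrays were still shared. When each comparison used a different vector array, the covariance of the log2 fold changes was 0.0226 at its lowest of 6 choices and 0.0336 at its highest, so chance values of shared arrays are argued against as the whole cause. An effect common to both transfected proteins, against an empty vector, stays open and was not tested separately.

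Of 154 small nucleolar, Cajal body and small nuclear RNAs 14 fell and 2 rose with Aire, a group shift lost with an estimated correlation (camera p = 0.000579, and p = 0.122), and 30 fell and 3 rose with MBD-VP16 (camera p = 3.17e-07, and p = 0.0368). A loss of short RNAs from the preparations cannot be told apart from other sources. The median over all 154 was −0.158 with Aire (95% interval −0.22 to −0.0467) and −0.315 with MBD-VP16 (−0.393 to −0.24). These intervals take the RNAs as independent and do not measure the spread between arrays. The rule set beforehand used the median alone, and the median with Aire lay on the side that counted against such a loss. Its interval reached across the bound of that rule, so the question is left undecided. The 191 clusters of 70 to 76 bases named only by their position did not fall as a group, with medians of 0.04 and 0, which goes against a loss of everything short, but their median signal of 4.39 lay below the 6.55 of all tested genes, so they do not settle it. A fall of the host genes cannot be told apart either, because few hosts were measured. The 7 hosts of RNAs that fell with Aire had a median of −0.0533 (95% interval over hosts −0.35 to 0.11). The 9 hosts with MBD-VP16 had one of −0.0733 (−0.443 to −0.00667). Of the hosts 1 of 7 was called lower with Aire and 3 of 9 with MBD-VP16, and 0 were called higher. Among all 17769 genes 814 and 1362 were called lower. The fallen small RNAs inside these hosts, 1 per host, had medians of −0.85 and −0.763. By the rule set beforehand both host medians counted against a fall of the hosts, but both intervals reached across its bound.

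The 6 arrays of each comparison can be split in 10 ways, which cannot give a share under 0.05. The labelled split, 1 of the 10, gave 1253 changed genes for Aire against vector, 2413 for MBD-VP16 against vector and 317 for MBD-VP16 against Aire, and the highest of the other splits gave 0 in each case. Each other split mixes arrays of both groups, so real differences between the groups enter its spread. Its 0 calls therefore do not give the number to be found without a difference.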
